A study of Mus musculus with 4 samples.

How the data were processed

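Heart tissue of C57BL/6 mice was profiled by RNA sequencing of total RNA in 4 libraries, 2 after sham surgery and 2 from a myocardial ischemia/reperfusion (I/R) injury model. Libraries are named by their group and the replicate number in their titles: sham 1, sham 2, I/R 3 and I/R 4. The labels do not say whether the 2 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The groups share no replicate number, so no paired fit was made.

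The files hold circular RNAs (circRNAs), which form when a downstream splice donor joins an upstream acceptor, so that a read across the junction shows the exons in reversed order. The authors deposited 1 file per library with the count of back-splice junction reads of each circRNA, the count of non-junction reads at the same splice sites and a fraction made from both. Per the file headers, each circRNA also has coordinates, a strand, a type (exon, intron or intergenic region) and a host gene, and the merged matrix adds a circBase identifier. Per the submitters' processing notes, BWA 0.7.5a-r405, HTSeq 0.9.1 and genome build mm9 were used, without a role for each tool; the circRNA caller is not given in the sources used here. The smallest deposited back-splice count was 2 reads in each library, so a circRNA listed at 0 had 0 or 1 read. The deposited fraction equals 2 times the junction reads over their sum with the non-junction reads, within the rounding of the file (largest deviation 0.0005). The merged matrix of back-splice counts differed from the per-library files in 0 cells. A further table gives the authors' own comparison, with log2 fold changes, p-values, adjusted p-values and score columns (a moderated t and a log odds), per the file headers; its contrast and settings are not stated there.

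Depth was low. The libraries held 1890 (sham 1), 1627 (sham 2), 1804 (I/R 3) and 1982 (I/R 4) back-splice reads, and 1 read was worth 529, 615, 554 and 505 CPM (back-splice reads scaled to the same total in every library), in that order. Shares of reads carry 95% Clopper-Pearson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. Read names put each library in 1 sequencing run and 4 lanes with similar numbers of reads, and 0 read names were shared between libraries. A chi-square test over the 102 circRNAs listed in all 4 libraries did not separate the libraries of a group (p = 0.913 for the sham pair and 0.377 for the I/R pair). Across groups p was 0.715 for sham 1 and I/R 3, 0.011 for sham 1 and I/R 4, 0.997 for sham 2 and I/R 3 and 0.0648 for sham 2 and I/R 4, so the test cannot tell whether a pair came from 1 heart, and it leaves out circRNAs at 0 in a library. Each library was counted as 1 replicate, as labelled.

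The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on back-splice counts, sham against I/R, with TMM factors (0.944, 1.155, 1.002 and 0.915 for sham 1, sham 2, I/R 3 and I/R 4), the total of back-splice reads as library size and Benjamini-Hochberg adjustment at 0.05. circRNAs needed 10 reads over the 4 libraries and a read in at least 2 of them, which left 158 of 1046. The standard error (SE) of a log2 fold change was taken from the F statistic. At few reads it can lie below counting error where libraries happen to agree. A change set against its SE is therefore no substitute for the p-value. The same test ran on reads summed per host gene label (153 of 710 labels). Where a group had no listed read, the fold sets the reads of the other group against a limit mean of 2.84 reads per library. That is the mean at which both libraries stay under 2 reads with a chance of 0.05. Reads of the other group are taken as exact, without counting error or spread between libraries, so the fold is no lower bound on the change. The limit mean was set after seeing the list minimum. Of 8 gene lists, those with at least 5 tested circRNAs were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry (limma 3.58.1). Of 709 host symbols, 708 were found in the RefSeq gene table by current name and 1 by an older name. Of 329 list genes, 328 were found there.

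The number of distinct circRNAs was the mean over 100 draws (seed 1) of thinning each library to 1627 reads. Group differences in values per library were tested with an exact two-sided permutation test, which cannot give a p below 0.333 with 2 libraries against 2. The named circRNAs follow a rule: those past an adjusted p of 0.05, else 8 per direction by p among circRNAs whose I/R values both lay on one side of both sham values; the 10 with the highest mean CPM; the 3 most abundant tested circRNAs of each list; and the 3 with the smallest p per direction in the authors' table. The results of 1 host gene are not reported here, while counts of calls and list tests include it. The groups, tests, gene lists, naming rule and the settings of the next sentence were set before the data were examined. Those settings were DESeq2 1.42.0, limma-voom, limma-trend with prior counts of 2 and 0.5, other normalizations and filters, the merged matrix and leaving out each library.

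Several steps were chosen after the counts had been seen. To learn how the authors' table was made, 8 settings of limma-voom (4 between-library methods, with and without TMM) were tried on all 1046 circRNAs, and 1 gave the table. A robust quasi-likelihood fit was also tried on the data before it was listed as an alternative, and made 0 calls. The comparisons of non-junction reads and of circular against non-junction reads, over the 102 circRNAs listed in every library, were added, with edgeR as above. For non-junction reads the library size was their sum over these 102 circRNAs. The second comparison tests the interaction of read type and group with a term per library. Removal of circRNAs at 0 in one library and 15 or more reads in another, removal of Ttn circRNAs and of circRNAs without a host, limma-voom without a filter, and the other splits of the 4 libraries into pairs were added too. The value of 15 was set after looking at the counts.

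The tests were tested on simulated counts before use. With dispersion near the estimate of 0.188 and the real depth, the circRNA test recovered 4.5% of 2-fold, 9.3% of 4-fold and 21.9% of 8-fold changes among about 160 tested circRNAs, and called 0.24% of unchanged ones. At 50 times the depth, with 1046 circRNAs tested, recovery was 4.8%, 47.5% and 89.1%. Non-junction reads of 102 circRNAs, simulated with an assumed dispersion, gave 71.5% recovery at 2-fold. The interaction test recovered 37.5% of 4-fold changes of circular reads. Those circular reads were simulated with an assumed dispersion far below the estimate of 0.188, and low counts were lifted to the list minimum. This recovery therefore does not hold for counts as variable as the estimate. The list test called 10 of 10 simulated doublings of the list of reported circRNA hosts and 0 of 29 unchanged lists. In these simulations circRNAs were drawn independently, while the real lists hold several circRNAs of a host such as Ttn. The rates may therefore not carry over to the real lists.

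Transcript sequences and exon models of GENCODE M21 (GRCm38) were used only for sequence similarity within a transcript (BLAST 2.17.0, e-value limit 1e-10) and for lengths and distances. Coordinates are those of the files (mm9, counted from 1) and were not converted. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 made the remaining values and the figures.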

Results

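The series compared circRNAs in mouse heart tissue after sham surgery (2 libraries) with those after ischemia/reperfusion (I/R), in which blood flow to part of the heart is stopped and then restored (2 libraries). The files list 1046 circRNAs with 7303 back-splice reads. Depth ranged from 1627 reads in sham 2 to 1982 in I/R 4. Of the 1046 circRNAs, 674 (64.4%) were listed in 1 library, 187 in 2, 83 in 3 and 102 in all 4. The 102 held 44.9% of the reads. The files place 951 circRNAs in exons, 52 in introns and 43 in intergenic regions without a host gene, and 709 (67.8%) carry a circBase identifier.

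Among host genes, Ttn, which encodes the giant sarcomere protein titin, had the most reads, 137, 65, 179 and 263 in sham 1, sham 2, I/R 3 and I/R 4 under its own host label. The most abundant circRNA overall lay in Ttn exons (chromosome 2, 76695961 to 76719896) and had a mean of 12434 ± 17584 CPM (SD, n = 2) in sham and 48889 ± 7209 CPM (SD, n = 2) in I/R. It was listed at 0 in sham 2. A circRNA of Strn3, a striatin scaffold protein (chromosome 12, 52748981 to 52762700, exonic), had 24181 ± 11002 CPM in sham and 28135 ± 4112 CPM in I/R (SD, n = 2). A circRNA of 1830 bp from Slc8a1, the cardiac sodium-calcium exchanger (chromosome 17, 82047149 to 82048978, exonic), had 18685 ± 9214 and 27182 ± 8652 CPM (SD, n = 2). The remaining leading circRNAs came from Ttn (2 more), Tulp4, the kinase gene Tlk1 and 3 spans on chromosome 14 without a host gene. The most abundant of these 3, from 55571083 to 55598399, had 47, 51, 42 and 61 reads and carries a circBase identifier. In all, 10 circRNAs without a host gene between 55563498 and 55610831 on chromosome 14 held 6.72%, 6.70%, 9.09% and 5.55% of the reads. Their spans match distances between exons of the paralogs Myh6 and Myh7, so their reads are uncertain.

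**Figure D1:**
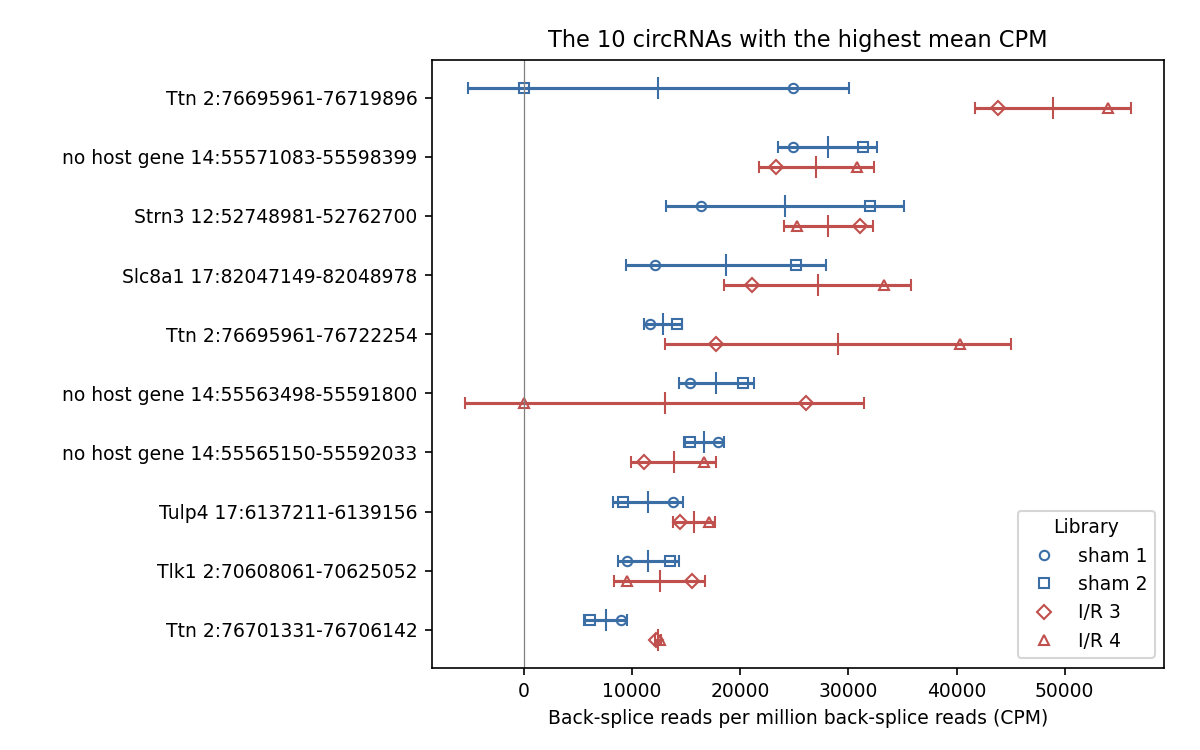
CPM of back-splice reads (horizontal axis) of the 10 circRNAs with the highest mean CPM, 1 symbol per library, with a tick and bar for the mean and SD of each group (n = 2). The leading Ttn circRNA was listed at 0 in sham 2 and had 79 reads in I/R 3, while the groups overlapped for the Strn3 and Slc8a1 circRNAs.

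The first comparison asked which circRNAs differed between I/R and sham. None of the 158 tested circRNAs passed an adjusted p of 0.05 in edgeR's quasi-likelihood test (smallest adjusted p = 0.660). At an unadjusted p under 0.05 there were 9 circRNAs, against 7.9 by chance; DESeq2 gave 0 calls and 6 such circRNAs, and limma-voom with the same filter 0 calls and 7. In 27 circRNAs both I/R values lay above both sham values and in 32 both lay below, 37.3% of those tested against 33.3% by chance. The circRNAs named next did not pass, and with so few reads their SEs can lie below counting error. Among those higher in both I/R libraries, the circRNA of Qk, an RNA-binding splicing regulator (chromosome 17, 10431758 to 10475846), and that of Cpeb3, a cytoplasmic polyadenylation element binding protein (chromosome 19, 37119012 to 37142781), each had 3, 4, 7 and 10 reads in sham 1, sham 2, I/R 3 and I/R 4 (log2 fold change 1.27, SE 0.40, edgeR adjusted p = 0.660). A circRNA of the Src-family kinase gene Yes1 (chromosome 5, 32942704 to 32966773) had 5, 3, 7 and 13 reads (log2 fold change 1.31, SE 0.52). The circRNA of the transcription factor gene Nfix (chromosome 8, 87295683 to 87296214) had 13, 14, 22 and 21 reads (log2 fold change 0.68, SE 0.32). Circular RNAs of Cdk8 and Med12l, both of the Mediator complex family, and of Zfp512 were listed in I/R alone, with 7 and 4, 4 and 6, and 5 and 5 reads. With these reads taken as exact, they lay 1.96-fold, 1.78-fold and 1.78-fold above the limit mean for sham. The chromosome 14 span from 55580566 to 55608918, with 4 and 8 reads, lay 2.13-fold above it. These folds allow for no counting error in the listed reads, so smaller changes or none were not excluded.

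Among the circRNAs lower in both I/R libraries, that of Rftn1, a lipid raft protein (chromosome 17, 50176266 to 50194952), had 12, 8, 6 and 4 reads (log2 fold change -0.97, SE 0.43). Those of the L-type calcium channel gene Cacna1c, the spectrin gene Sptbn1, the Ras pathway inhibitor Spred2 and the GTPase-activating gene Arhgap26 had log2 fold changes from -2.31 to -2.01, with SEs from 1.04 to 1.17. Without an I/R library their fitted values ranged from -5.74 to -1.18, the lowest where the I/R library left had no listed read, which is no bound on the fold. Circular RNAs of Dgkd, a diacylglycerol kinase (8 and 3 reads), and Arhgap10, a GTPase-activating gene (4 and 6 reads), were listed in sham alone. Taken as exact, these reads lay 1.91-fold and 1.74-fold above the limit mean for I/R, again no lower bound on the change. With 2 libraries per group at this depth the test recovered 21.9% of simulated 8-fold changes, so differences of the sizes named were not detectable with confidence. Without a filter edgeR made 3 calls, each listed in a single library, among them Brd9 (23 in I/R 3) and a chromosome 14 span from 55568175 to 55594254 (28 in I/R 3). Without sham 1 the leading Ttn circRNA passed (adjusted p = 3.92e-05, edgeR), and without I/R 3 the chromosome 14 span from 55563498 to 55591800 (adjusted p = 0.00479, edgeR), each listed at 0 in the library left alone in its group. In the other edgeR settings their adjusted p was at least 0.587 and 0.696. The circRNAs named as called without a filter were chosen after their values were seen.

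Reads summed per host gene gave the same outcome. None of 153 hosts passed (smallest adjusted p = 0.867, edgeR), and 8 had an unadjusted p under 0.05 against 7.65 by chance; DESeq2 gave 0 calls with 4 and limma-voom 0 calls with 8. The 8, listed here after their values were seen, were Cdk8, Zfp512, Med12l and the joint label Mir684-1/Ttn, seen in I/R alone, Camsap1, Dgkd and Hnrnpa2b1, seen in sham alone, and Cacna1c with 7, 7, 0 and 2 reads (log2 fold change -2.61, SE 1.09). Ttn had a log2 fold change of 1.19 with an SE of 0.78. Strn3 had 0.35 with an SE of 0.52. Without a filter the host Brd9 passed in edgeR (23 reads in I/R 3), and limma-voom passed Strn3 (adjusted p = 8.39e-05), Slc8a1 (adjusted p = 0.000158) and Cdk8 (adjusted p = 0.0141).

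The gene lists grouped hosts by function or cell type. Of sarcomere hosts, 12 circRNAs were tested, 5 with a fitted change above 0 and 7 below (median log2 fold change -0.35, camera in limma adjusted p = 0.873). The median was -0.14 without sham 1, -0.68 without sham 2, -0.15 without I/R 3 and 0.16 without I/R 4. Of its Ttn members, the leading circRNA was fitted at 1.96 (SE 1.77), the span from 76695961 to 76722254 at 1.33 (SE 0.62) and that from 76701331 to 76706142 at 0.80 (SE 0.43). Without I/R 4 the span to 76722254 was fitted at 0.46, and without sham 2 the leading circRNA at 0.86 and the span to 76706142 at 0.35. Below 0, and named after their values were seen, were the Ttn spans from 76695961 to 76726144 at -0.64 (SE 0.39) and to 76748010 at -0.57 (SE 1.85). Of calcium and ion handling hosts, 7 were tested, 4 above 0 and 3 below. The median was 0.42 and the mean -0.11, with camera's direction down (adjusted p = 0.873). Its abundant members were those of Slc8a1 (0.72, SE 0.55), Asph (-0.21, SE 0.32) and the ryanodine receptor gene Ryr2 (0.42, SE 0.42). Slc8a1 was fitted at 0.35 without sham 1 and 0.21 without I/R 4, Ryr2 at 0.14 without sham 2 and 0.10 without I/R 4, and Asph at -0.37 without sham 2 and -0.42 without I/R 3. The list's median was 0.73 without I/R 3. Of reported cardiac or widely conserved circRNA hosts, 26 were tested, 18 above 0 and 8 below (median 0.40). Camera gave an adjusted p = 0.424, camera with an estimated correlation an adjusted p = 0.737 and fry an adjusted p = 0.455. The list's median was 0.18 without sham 1 and 0.21 without I/R 4. The list names Qki, but the circRNA labelled Qk (1.27, SE 0.40) was not matched to it, so the results of this list leave it out. This list passed with at least 20 reads per circRNA (17 tested, adjusted p = 0.0216) and without I/R 3 (adjusted p = 0.028). With at least 20 reads the median was 0.42, with 14 of the 17 above 0. Leaving out Ttn circRNAs as well, the median was 0.42, with 10 of 12 above 0 and adjusted p = 0.0565. At 20 reads calcium and ion handling hosts were not tested, nor sarcomere hosts once Ttn circRNAs were left out. The adjustment then covered fewer lists than the 3 of the main fit. The value of 0.0565 covers this list alone and equals the unadjusted one, so the adjusted p-values of these settings are not directly comparable. The highest adjusted p of any setting was 0.875, without sham 1. With all 4 libraries and the filter of 10 reads, 0 circRNAs passed in each of the 3 lists adjusted over the list alone, as over all circRNAs tested. Adjusted over the list alone, without sham 1 there was 1 in the sarcomere list and 1 in that of reported hosts, and without I/R 3 there were 2 and 1.

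The other 5 lists had fewer than 5 tested circRNAs. Mitochondrial and energy metabolism had 2, Ogdh (log2 fold change 0.18, SE 0.34) and the fatty acid transporter Cd36 (-0.70, SE 0.59). Endothelial markers had 2, Pecam1 (-0.55, SE 1.40) and Ptprm (0.02, SE 1.43), and the hypoxia and acute injury list had 1, Nfkb1 (-0.20, SE 0.34). Fibroblast and leukocyte hosts had 0. Reads of leukocyte hosts were 0, 2, 0 and 0 in sham 1, sham 2, I/R 3 and I/R 4, and those of fibroblast and matrix hosts 7, 5, 0 and 5.

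The size of the circRNA repertoire was compared next. At 1627 reads per library there were 462 and 403 distinct circRNAs in sham and 389 and 436 in I/R, a mean of 432.7 ± 42.0 against 412.8 ± 33.4 (SD, n = 2, exact two-sided permutation p = 0.667, smallest possible 0.333). The difference, -19.9 in I/R minus sham, turned to 9.75 without sham 1 and 3.71 without I/R 3. This count keeps circRNAs thinned to 1 read in sham 1, I/R 3 and I/R 4, while the list minimum leaves none in sham 2. With at least 2 reads after thinning there were 402.6 and 403 in sham 1 and sham 2. In I/R 3 and I/R 4 there were then 355.1 and 363.7 (exact two-sided permutation p = 0.333, the smallest possible). Single reads come off the 1627 in these libraries and in sham 1, while sham 2 keeps all 1627. Seen in both libraries of one group and neither of the other were 39 circRNAs for sham and 32 for I/R, 71 in all, against 55 and 61 in the other splits of the 4 libraries into pairs. With at least 5 reads the count was 1, against 2 and 2.

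The 10 leading circRNAs took a larger part of the reads in both I/R libraries, 21.6% (95% interval 19.7 to 23.6) in I/R 3 and 24.0% (22.1 to 25.9) in I/R 4, against 15.6% (13.9 to 17.3) in sham 1 and 16.7% (14.9 to 18.6) in sham 2. The means were 22.8 ± 1.66% and 16.1 ± 0.82% (SD, n = 2, exact two-sided permutation p = 0.333, the smallest the design allows). Without Ttn circRNAs the shares were 14.8%, 18.3%, 19.2% and 18.1% in sham 1, sham 2, I/R 3 and I/R 4, and the groups overlapped. The 31 circRNAs with Ttn in the host label held 7.25% (6.12 to 8.51), 4.00% (3.10 to 5.06), 10.03% (8.69 to 11.5) and 13.98% (12.5 to 15.6) of the reads. The leading Ttn circRNA alone was listed with 47, 0, 79 and 107 reads.

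**Figure D2:**
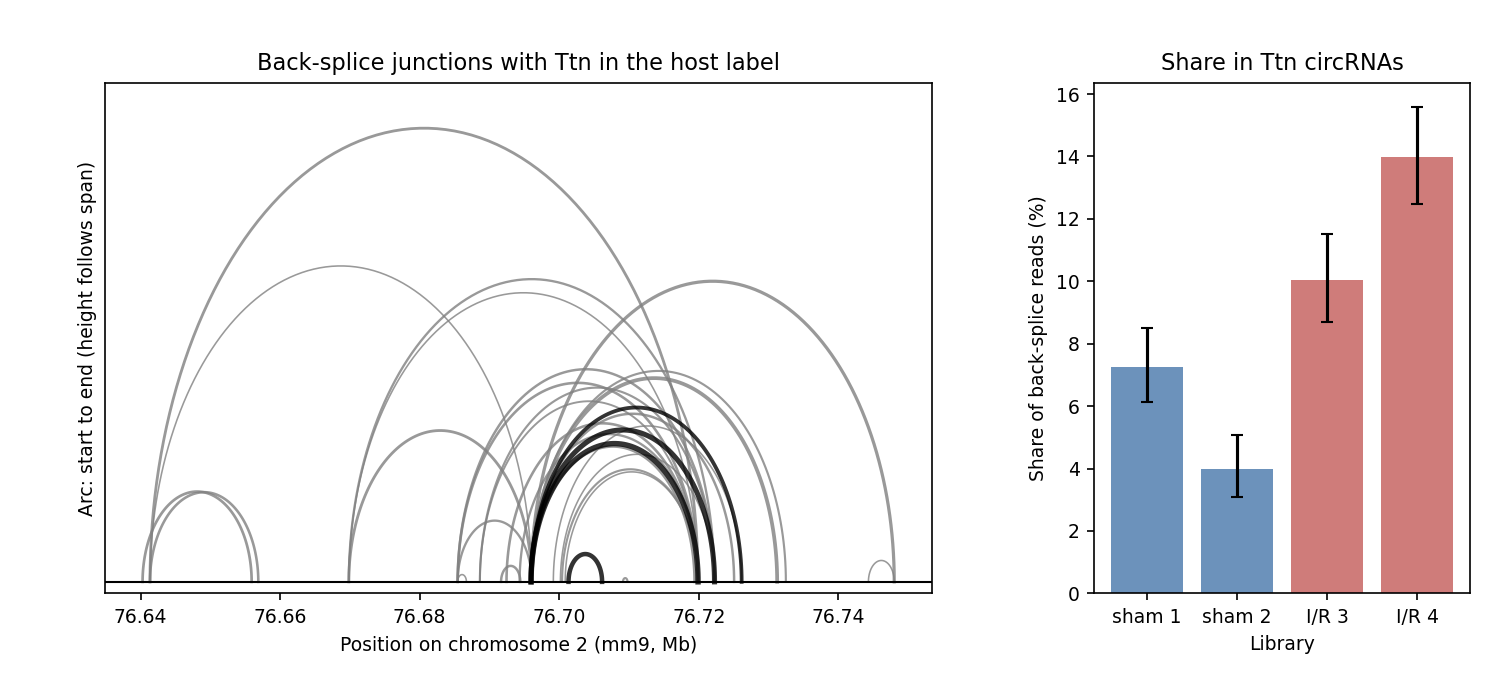
Left, each of the 31 back-splice junctions with Ttn in the host label as an arc from start to end on chromosome 2 (mm9, Mb), wider with more reads and black at 30 or more. Right, the share of back-splice reads in these circRNAs per library with 95% Clopper-Pearson intervals, from 4.00% in sham 2 to 13.98% in I/R 4.

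The authors' deposited table was set beside the refit. It lists 11 circRNAs with an adjusted p under 0.05, 7 higher and 4 lower in I/R. In the authors' deposited table the leading Ttn circRNA had the smallest p (log2 fold change 4.34, adjusted p = 0.00222), followed by the chromosome 14 span from 55580566 (3.61), Cdk8 (3.52), Arhgap10 (-3.46), Zfp512 (3.44), Med12l (3.42) and Dgkd (-3.44). The 3 lower circRNAs with the smallest p in the authors' deposited table were those of Arhgap10, Dgkd and the span from 55563498 to 55591800 (-2.73). A limma-voom fit with TMM factors on all 1046 circRNAs gave its log2 fold changes to within 2.1e-14. Of the 11, 9 had no listed read in one group. The edgeR test covered 8 of the 11, of which 6 had an unadjusted p under 0.05 and none passed (smallest adjusted p = 0.660). Of the 158 circRNAs tested in both, 148 had the same sign. The same limma-voom fit after the filter of 10 reads, which kept 8 of the 11, made 0 calls.

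Non-junction reads at the splice sites of the 102 circRNAs listed in every library were compared last, a comparison added after the counts had been seen. These reads come from linear transcripts or from within the circle. They fell in I/R at 5 circRNAs and rose at 4 (edgeR, adjusted p under 0.05; 27 at an unadjusted p under 0.05). At the Slc8a1 circRNA there were 497 and 672 non-junction reads in sham and 279 and 282 in I/R (log2 fold change -0.97, SE 0.18, adjusted p = 3.37e-05). Lower too were Dysf, a membrane repair gene (-0.92, SE 0.19), the kinase gene Map4k2 (-0.95, SE 0.22) and the NF-kappa-B subunit gene Nfkb1 (-0.83, SE 0.25). Higher were Cpeb3 (0.63, SE 0.18), the endosomal gene Rabep1 (0.59, SE 0.20), the muscle gene Mlip (0.55, SE 0.19) and Tmem245 (0.53, SE 0.18). Without TMM the median log2 fold change of the 102 moved from -0.036 to -0.23, and 4 calls were left, Slc8a1, Dysf, Map4k2 and Nfkb1, all lower. A few sites weigh heavily on the library size. Of 56671 non-junction reads in sham 1, 17212 lay at Tpm1 and 14051 at the chromosome 14 span from 55571083. The number of calls was 10 without sham 1, 1 without I/R 4 and 0 without sham 2 or without I/R 3.

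The circular share at the Slc8a1 circRNA was 9.67 ± 1.70% in sham and 26.6 ± 7.41% in I/R (SD, n = 2). The change of circular against non-junction reads did not pass in edgeR (log2 ratio change 1.69, SE 0.32, adjusted p = 0.0517). It passed without sham 2 (log2 ratio change 1.77, adjusted p = 0.00421), and without I/R 4 the log2 ratio change was 1.20 (adjusted p = 0.967). Of the 102 circRNAs 0 passed in this test, with 4 at an unadjusted p under 0.05.

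**Figure D3:**
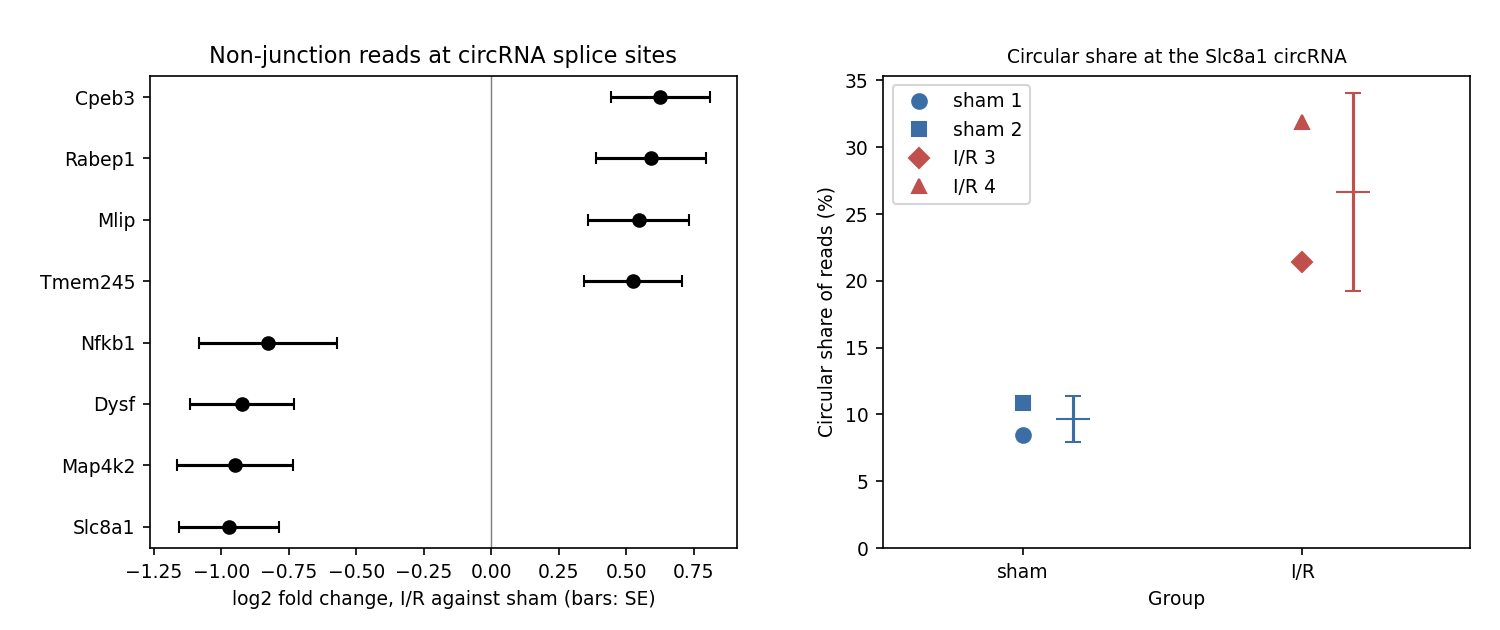
Left, log2 fold changes in I/R against sham of non-junction reads at 8 of the 9 circRNAs past the threshold (points, with SE bars). Right, the circular share in percent at the Slc8a1 circRNA per library with the mean and SD of each group beside (n = 2), from 8.47% in sham 1 to 31.9% in I/R 4.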

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

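Chosen after seeing the data were limma-voom without a filter, the robust fit, the removals of circRNAs, and all settings of the non-junction and circular against non-junction comparisons. Against 0 calls in the main test, circRNA calls numbered 3 without a filter and 11 in limma-voom without a filter; leaving out a library gave 0 to 1. Host calls numbered 1 without a filter, 3 in limma-voom without a filter and 0 in the other settings. List calls went from 0 to 1 with at least 20 reads, and leaving out a library gave 0 to 1. The difference in distinct circRNAs (I/R minus sham) was -19.9 and ranged from -49.6 to 9.75 without a library. It was -17.5 without thinning and -43.4 at 2 reads after thinning. The list minimum had already put that limit on sham 2, so with it the same limit holds in every library. The reads counted are still not equal, since sham 2 keeps all 1627 and the other libraries lose their single reads. On/off circRNAs went from 71 to 1 at 5 reads. Non-junction calls went from 9 to 4 by library size only and ranged from 0 to 10 without a library, and circular against non-junction calls from 0 to 1. The difference in the share of the 10 leading circRNAs kept its sign in all settings run but went from 6.66 percentage points to 2.07 without Ttn circRNAs, 4.18 without the leading one, 4.57 without circRNAs at 0 in one library and 15 or more in another, and 3.65 for the 1 leading circRNA. Without TMM the median log2 fold change moved from 0.060 to -0.044 for circRNAs and from -0.025 to -0.17 for hosts. The cause was not tested, beyond the fewer libraries or other circRNAs that a setting holds by construction. A lone library in a group is assumed to vary like the other group, and leaving one out was not run for on/off circRNAs.

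Of 547 values of the 33 circRNAs of the naming rule under other settings, 519 kept direction and side of the threshold, 10 passed it and 18 turned, in 7 circRNAs. The log2 fold change of Ptprm turned from 0.02 to -0.97 (limma-voom), -0.31 and -0.93 (limma-trend, prior counts 2 and 0.5), -0.15 (library size only), -0.014 (no filter), -0.10 (5 reads in 2 libraries) and -0.96 (limma-voom without a filter). The chromosome 14 span from 55571083 turned from 0.09 to -0.055 (library size only), -0.040 (5 reads in 2 libraries) and -0.039 (20 reads). Without a library, values ranged from -0.48 to 0.88 for Ptprm, -0.27 to 0.21 for that span, -7.99 to 0.55 for the span from 55563498, -0.61 to 0.10 for the span from 55565150, -0.17 to 0.44 for Tlk1, -0.19 to 0.32 for Ogdh and -0.68 to 0.16 for the sarcomere median, and Pecam1 turned to 0.36 without I/R 4. Of 45 values of the 9 non-junction calls, 34 missed the threshold, 11 kept it and 0 turned. For back-splice reads of named circRNAs, log2 fold changes without a library were 0.051 to 0.66 for Strn3, 0.087 to 1.01 for Tulp4 and 0.74 to 1.71 for Yes1. Those back-splice values were -1.40 to -0.64 for Rftn1, -0.58 to -0.046 for Nfkb1 and -1.31 to -0.41 for Cd36. In simulations depth limited the recovery of 4-fold and 8-fold changes in the circRNA test, while recovery of 2-fold changes was 4.5% at this depth and 4.8% at 50 times.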

Other observations

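Tests chosen only after their result was seen are those of sampling and of the whole Ttn stretch for the Ttn zero, the count per host and the exon lengths, the effect of the filter and the splits of the libraries; the test of repeats per circRNA, that of exon distances and that of pooled reads were set before their results. The 31 Ttn circRNAs used 16 starts and 15 ends between 76640288 and 76748010 on chromosome 2 (mm9), 0 of them with a circBase identifier. A single start at 76695961 was shared by 8 circRNAs with 101, 40, 130 and 212 reads in sham 1, sham 2, I/R 3 and I/R 4, and the most used end, 76719896, by 9 circRNAs with 52, 4, 95 and 121 reads, of which those other than the leading circRNA held 5, 4, 16 and 14. On the minus strand of the files, the shared start is the back-splice donor.

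The leading Ttn circRNA was listed at 0 in sham 2, against 47 reads in sham 1, while the span from the same start to 76722254 had 23 and 22 reads in these libraries, a rate ratio of 1.21 (exact 95% interval 0.65 to 2.29), which argues against less back-splicing over the whole stretch. From that span 30.8 reads would be expected in sham 2, and the Poisson chance of 0 or 1 is 1.4e-12, which, as counting error only, argues against sampling of independent reads and leaves few molecules with many reads each open. Loss of junctions in hosts with repeated sequence stays open. Hosts of 4 circRNAs at 0 in one library and 15 or more reads in another were compared with those of 14 others. The 4 had more self-similar sequence (exact one-sided permutation p = 0.0441). With 1 value per host, a count added later, the exact one-sided permutation p was 0.0286. The Ttn circRNA to be explained is itself 1 of the 4, and the value of 15 was set after looking at the counts. The test therefore cannot decide whether such loss caused this zero. Also, 1 host counts as 2 of the 4, and Brd9 had none. Ttn is in both sets per circRNA, and only in the zero set per host. What sets sham 2 apart stays open, and a difference between these hearts was not tested.

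The 10 circRNAs without a host gene on chromosome 14 span 26080 to 29358 bp, and all 10 spans equal a distance from a Myh6 to a Myh7 exon edge in GRCm38, where random spans gave a mean of 0.63 matches and at most 6. With 100000 sets of random spans p was 1e-05, the smallest they can give. In all 10 the Myh7 exon is as long as the next Myh6 exon, and counted from the last exon of each gene 8 were a step of 1 exon, while the spans from 55580566 and 55582733 were a step of 0. A candidate explanation is that reads of ordinary exon junctions, in genes whose exons are near copies, were placed on both paralogs and read as back-splices. Any pair of exons of these genes counted as a match, so a real circle joining them would match too. The p above therefore cannot tell these explanations apart. Among the 10, only the span from 55571083 carries a circBase identifier. Read sequences were not analysed here, so circles or transcripts that join the genes stay open, and no biological explanation was tested.

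The 11 calls of the authors' deposited table may rest on a spread set by circRNAs with few reads. The same limma-voom fit without circRNAs under 10 reads could test 8 of them and called 0, and its prior degrees of freedom went from 36.0 to 4.32. With no spread between libraries beyond counting error, an exact binomial test of pooled reads, adjusted over all 1046 circRNAs, passed 2 of the 11, Ttn and Dgkd. Dgkd passed at an adjusted p of 0.0483 in that test, and the Ttn circRNA had 47 and 0 reads in sham. The test passed 7 circRNAs in all, among them Brd9 with 23 reads in I/R 3 alone. A pass can therefore reflect spread between libraries, which the test leaves out. Of the 3 splits of the libraries into pairs, 1, the real one, gave as many calls, with 0 as the highest of the others, and 3 splits are too few for a share under 0.05. An effect of I/R on these circRNAs was not excluded.

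For the 9 calls in non-junction reads, 1 of the 3 splits, the real one, gave as many, with 0 as the highest of the others, which is too few splits for a share under 0.05.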
